A study of Mus musculus with 15 samples.

How the data were processed

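Gene expression was measured by RNA sequencing in 15 libraries of mouse mPFC dissected by atlas coordinates. Libraries were made with the SMARTer Ultra Low Input V4 kit, which does not keep the strand of a transcript. The extraction text also speaks of sorted cells, although the source of each sample is dissected tissue. The deposited table holds raw counts per Entrez gene identifier, with 1 column per library and no normalization. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.3.0 and the mm10 build were used; the counting program, the annotation and any filter are not given in the sources used here. The table has 27179 identifiers, of which 4671 have 0 counts and 25275 were matched to a gene symbol through a RefSeq annotation of the same build, covering 99.7% of counts. Depth was 44254906 to 57929503 counts per library, and the biological coefficient of variation between libraries was 0.112, so for genes above a few CPM the spread between libraries, not counting error, set the precision.

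Groups followed the labels for ABX treatment and extinction stage, with 3 libraries in pre-extinction non-ABX, where the labels have no replicate 2, and 4 in each other group. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 16816, libraries were scaled by TMM factors (0.969 to 1.03), and a quasi-likelihood model with 4 group means and no covariate was fitted to all 15 libraries. The 4 pairwise contrasts and the interaction were tested two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors are the fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and list scores use log2 CPM with a prior count of 2.

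Before the data were examined, 38 gene lists with 994 memberships were fixed, covering synaptic, channel, signalling, stress, metabolic and cell type genes, along with the contrasts, the tests, the naming rule and the other settings to try. Lists with at least 5 tested members were tested by camera in limma 3.58.1 on voom values, a competitive two-sided test with a preset correlation of 0.01, adjusted over the 38 lists within each contrast. With the correlation estimated from the data 0 lists passed in any contrast. Printed list medians are of edgeR fold changes, and medians with a library left out are of voom fold changes. List scores were also compared by two-sided exact permutation of the libraries within the groups compared.

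Genes were named by a rule fixed in advance. In each pairwise contrast it took, among called genes with an ordinary symbol, a mean of at least 1 CPM and libraries that did not overlap between groups, the 10 largest positive and the 10 largest negative fold changes. In each called list, and always in the immediate early gene list, it took the 3 members with the smallest unadjusted p. With fewer than 10 calls it took all called genes and the 5 genes of smallest p in each direction as values that did not pass. For the interaction it took up to 20 called genes or otherwise the 5 of smallest p. Some genes that the rule takes are not reported here.

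Other settings fixed in advance were DESeq2 1.42.0, voom with sample quality weights, RLE scaling, no filter, a stricter filter at a mean of 1 CPM, the replicate number as a block, 1 surrogate variable from sva 3.50.0, the compared groups alone, camera with an estimated correlation, fry, and each library left out in turn. After seeing the data, a GC-content correction (a spline with 5 degrees of freedom per library on the GC content of the longest transcript, possible for 91.2% of tested genes and 99.3% of list genes) and the omission of 3 libraries with most blood transcripts were added, as were the ABX and stage contrasts averaged over both levels of the other factor. All per-sample columns were used. The pipeline was tested on simulated data before the fits, and 1 of these tests was run again afterwards with another seed.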

Results

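Bulk RNA of dissected mouse medial prefrontal cortex (mPFC) was sequenced in 15 libraries from C57BL/6J mice. The mPFC is a cortical region in which fear extinction, the learned decline of a conditioned fear response, is regulated. The mice were labelled as ABX treated or not, ABX being the field's usual abbreviation for a mixture of antibiotics, and were sampled before or after fear extinction. The groups were pre-extinction non-ABX (n = 3, replicates 1, 3 and 4), pre-extinction ABX (n = 4), post-extinction non-ABX (n = 4) and post-extinction ABX (n = 4). Total counts per library ran from 49231174 to 57929503, from 44254906 to 55058397, from 47863644 to 53892681 and from 45832528 to 48830512 in these groups. Each library had counts for 19621 to 19939 of the 27179 gene identifiers, and 16816 genes were tested. Levels are given in CPM, counts scaled to a common library size,, as mean ± SD over the libraries of a group, and differences as log2 fold changes. Named genes are protein-coding genes of mouse build mm10 unless stated otherwise. The p-values measure the spread between these libraries, and whether each library is 1 animal is not given in the sources used here.

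The comparison of ABX with non-ABX libraries before extinction asks how mPFC expression differed with the treatment ahead of extinction. Myh6 (Entrez 17888, chromosome 14, 54941921 to 54968017), the alpha heavy chain of cardiac myosin, fell from 4.87 ± 0.175 CPM (SD, n = 3) to 1.45 ± 0.317 CPM (SD, n = 4). Its log2 fold change was -1.74 (SE 0.17, edgeR adjusted p = 2.5e-04), and reads shared with its close paralog Myh7 could not be separated in a table of counts. Genes of brain endothelial cells, which form the blood-brain barrier, fell as a group: 26 of 27 had a negative log2 fold change (median -0.33, camera adjusted p = 1.5e-10), with an adjusted p = 0.89 with an estimated correlation. Genes of pericytes and vascular smooth muscle, the contractile cells of the vessel wall, fell as well, with 15 of 16 negative (median -0.29, adjusted p = 9.6e-06, and adjusted p = 0.89 with an estimated correlation). In the endothelial list 0 genes passed over all genes tested and 13 fell when adjusted over the list alone, and in the pericyte list these counts were 0 and 8.

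Single vascular genes stood as follows, none of them past the edgeR test over all genes (adjusted p = 0.311 for each gene in this paragraph unless given). Podxl, a sialomucin of the endothelial surface, was at 33.8 ± 4.47 CPM with ABX and 49.0 ± 6.01 CPM without (log2 fold change -0.53). Sox17, an arterial transcription factor, had -0.84, and Flt1, a receptor for vascular endothelial growth factor, -0.50. The smooth muscle genes Acta2, Tagln and Des had -0.89, -0.53 and -1.11. Pltp, a phospholipid transfer protein, had 17.7 ± 4.68 against 30.9 ± 6.89 CPM (-0.80). Fmo2 had -0.74 and Srarp -1.30, while Utp14b had 0.50, Car13 0.69, Krt9 0.41, Pter 0.53 and Tmem255a 0.36. In the list of ionotropic glutamate receptors and the postsynaptic density, which fell as a group, 26 of 36 genes were negative (median -0.21, camera adjusted p = 0.00499, and adjusted p = 0.89 with an estimated correlation). Cacng2, an AMPA receptor auxiliary subunit, had -0.36, and the scaffold genes Shank1 and Dlgap4 had -0.62 and -0.50; 0 members passed either over all genes or when adjusted over the list alone. With the GC-content trend removed, an alternative chosen after seeing the data, the list median was -0.05 (adjusted p = 0.013), Shank1 had -0.21 and Dlgap4 -0.17. Mitochondrially encoded transcripts rose as a group, with 12 of 13 positive (median 0.29, adjusted p = 0.0198, and adjusted p = 0.89 with an estimated correlation), and again 0 members passed over all genes or when adjusted over the list alone. The ribosomal RNAs mt-Rnr2 and mt-Rnr1 had 0.41 (adjusted p = 0.321) and 0.35 (adjusted p = 0.365), and mt-Nd6, whose strand the library kit does not keep apart, had 0.34 (adjusted p = 0.347). With the GC-content trend removed this list no longer passed (median 0.05, adjusted p = 0.603). Of 32 activity-regulated immediate early genes, which neurons switch on when they fire, 16 were positive and 16 negative. Their median was -0.01 and mean -0.03 while the camera test leaned upward (adjusted p = 0.872), and 0 passed over all genes or adjusted over the list alone. Gadd45g had -0.74 (-0.36 with the GC-content trend removed), Tiparp 0.48 and Btg2 0.82.

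Before extinction edgeR called 1 gene in all, with 2686 genes at an unadjusted p under 0.05 where chance gives 841, and the libraries of both groups did not overlap for 1136 genes, 6.76% against 5.71% by chance. Here and in the other comparisons the 841 is an average that takes no account of genes that move together. Another split of these libraries called 2757 genes past the adjusted threshold, so the excess over 841 does not by itself show a difference. The other 34 lists had camera adjusted p from 0.058 to 0.872. DESeq2 called 15 genes, and without replicate 4 of the pre-extinction ABX group edgeR called 28, and 2 without replicate 3 of the pre-extinction non-ABX group. The mitochondrial list no longer passed without pre-extinction ABX replicate 1 (median 0.14, adjusted p = 0.231) or pre-extinction non-ABX replicate 3 (0.11, adjusted p = 0.257), and the glutamate receptor median was -0.12 and -0.15 without the same libraries; without pre-extinction ABX replicate 3 there were 7 lists, and without pre-extinction non-ABX replicate 3 there were 8.

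**Figure D1:**
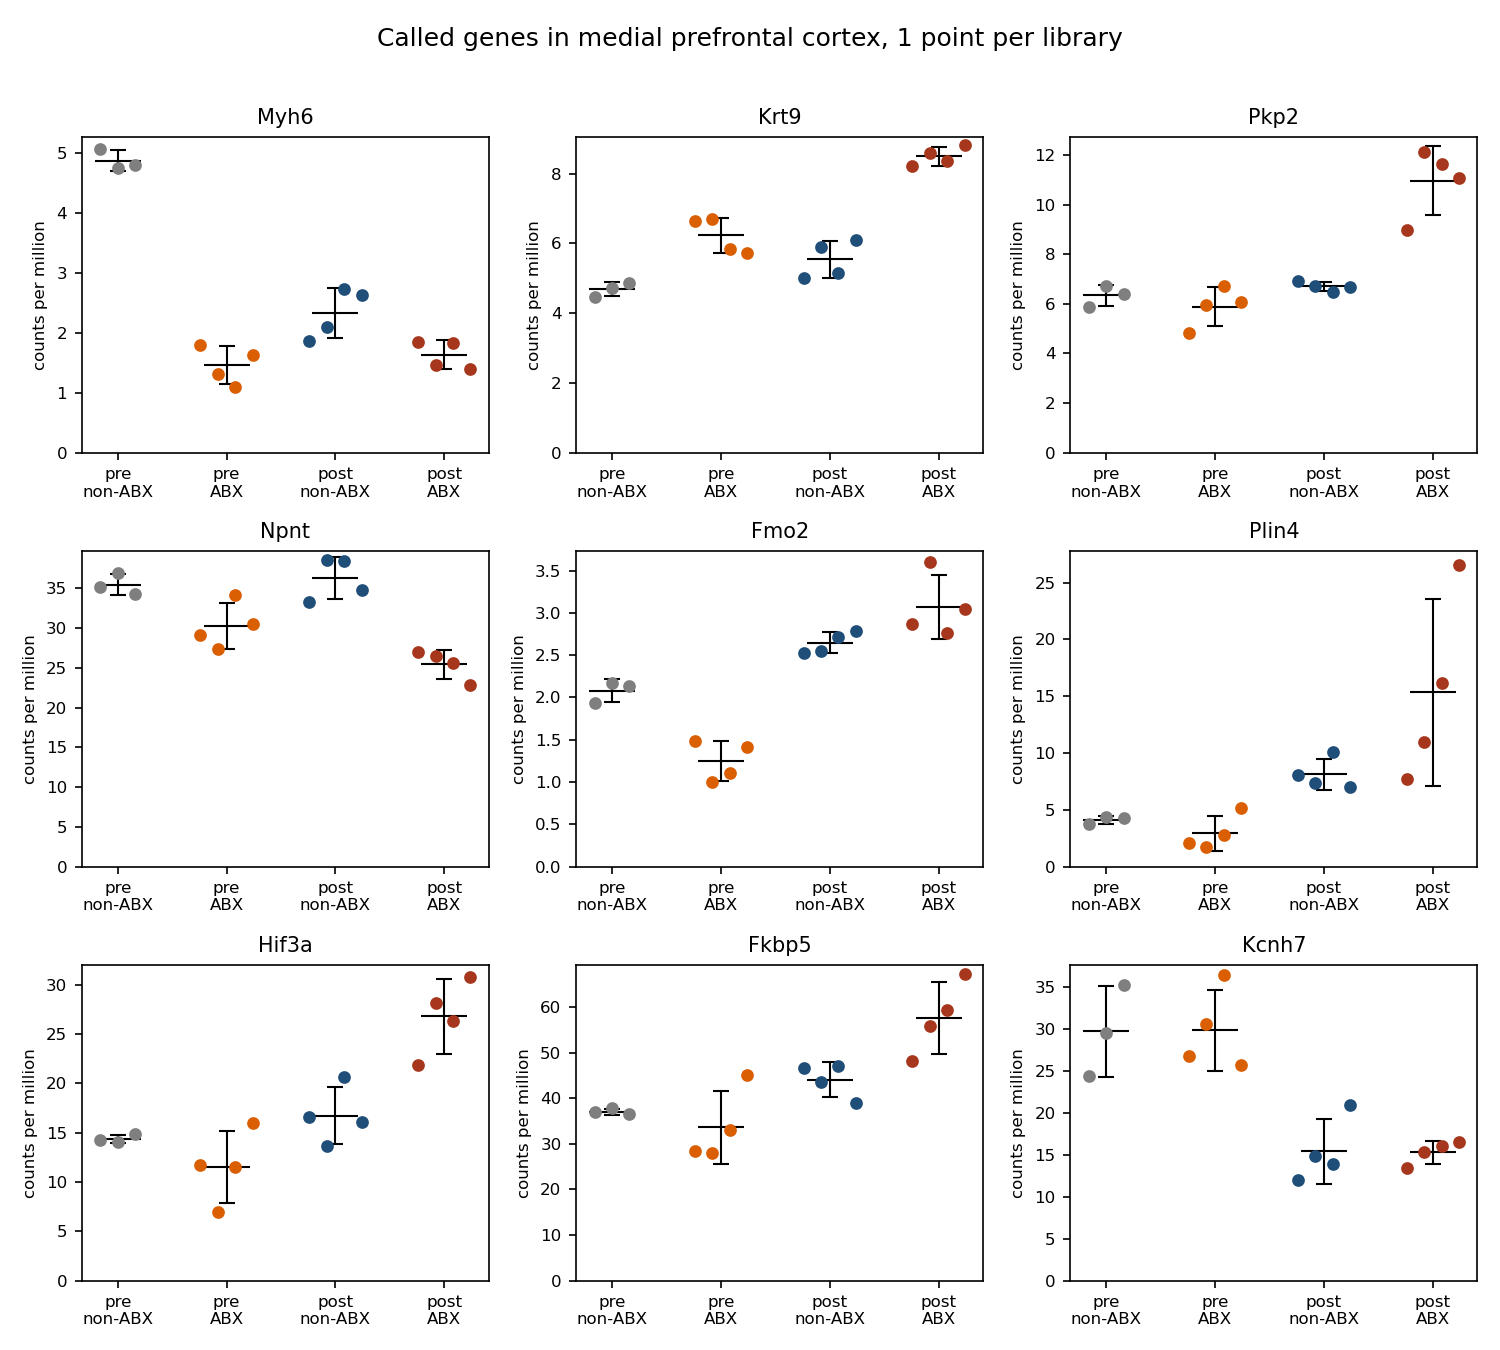
Level of 9 called genes in CPM (y axis) in the 4 groups (x axis), with 1 point per library, the mean as a long line and the SD as bars. Myh6 lies between 4.74 and 5.07 CPM in the 3 pre-extinction non-ABX libraries and between 1.09 and 1.79 CPM in the 4 pre-extinction ABX libraries.

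After extinction, the ABX comparison asks how treated and untreated cortex differed following extinction. Krt9 (Entrez 107656, chromosome 11, 100186781 to 100193246), a keratin, rose with ABX from 5.54 ± 0.534 to 8.50 ± 0.269 CPM (SD, n = 4 each), a log2 fold change of 0.62 (SE 0.09, edgeR adjusted p = 0.0449). Pkp2 (Entrez 67451, chromosome 16, 16213345 to 16272712), a plakophilin of cell junctions, rose from 6.70 ± 0.174 to 11.0 ± 1.39 CPM (0.71, SE 0.11, adjusted p = 0.0455). Npnt (Entrez 114249, chromosome 3, 132881745 to 132950291), the matrix protein nephronectin, fell from 36.3 ± 2.63 to 25.5 ± 1.85 CPM (-0.51, SE 0.08, adjusted p = 0.0455). Endothelial genes fell again as a group, with 25 of 27 negative (median -0.32, camera adjusted p = 6.4e-12, and adjusted p = 0.527 with an estimated correlation). Of 16 pericyte and smooth muscle genes 14 were negative (median -0.33, adjusted p = 3.1e-06, and adjusted p = 0.527 with an estimated correlation). Over all genes 0 members of either list passed, and when adjusted over the list alone 15 endothelial and 8 pericyte genes fell.

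Among single vascular genes, given as values that did not pass, Kdr and Eng, receptors of the vascular endothelium, had -0.48 and -0.70, and Acta2 and Tagln -0.91 and -0.55 (adjusted p = 0.165 each). Myh11, smooth muscle myosin, had -0.74 (adjusted p = 0.197). Podxl was at 34.0 ± 2.51 against 49.3 ± 2.90 CPM (-0.53) and Pltp at 17.8 ± 2.44 against 33.8 ± 2.50 CPM (-0.92), with Slc38a5 at -0.77 (adjusted p = 0.0645 for these 3). Mmrn2, an endothelial matrix gene, had -0.83 (adjusted p = 0.0786) and Pdzrn3 -0.46 (adjusted p = 0.0766). On the other side Matn2 had 0.38 (adjusted p = 0.0645), Zcchc12 0.41 (0.101), Rhou 0.39 (0.116) and Mrap2 0.47 (0.125).

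After extinction 5 lists of neuronal genes were called lower in ABX libraries, each by a small median, while GABA (median -0.05, camera adjusted p = 0.428) and metabotropic glutamate receptor genes (-0.05, 0.253) were not. For ionotropic glutamate receptors and the postsynaptic density, 25 of 36 genes were negative (median -0.14, camera adjusted p = 0.00353, and adjusted p = 0.637 with an estimated correlation), with 1 fallen when adjusted over the list alone. Cacng2 had -0.39, Dlgap4 -0.40 and Shank1 -0.47. Synaptic vesicle and release genes had 26 of 36 negative (median -0.11, adjusted p = 0.00289, and adjusted p = 0.637 with an estimated correlation), with 2 fallen when adjusted over the list alone; Syt2, a calcium sensor of fast release, had -0.51 (adjusted p = 0.125), Sv2c -0.46 and Rims3 -0.56. Calcium channel and signalling genes had 28 of 43 negative (median -0.08, adjusted p = 0.00289, and adjusted p = 0.637 with an estimated correlation), and 5 fell and 1 rose when adjusted over the list alone. Atp2b2, a plasma membrane calcium pump, had -0.42, Camkk2 -0.28 and the T-type channel gene Cacna1i -0.41. Potassium channels had 31 of 38 negative (median -0.10, adjusted p = 0.00193, and adjusted p = 0.527 with an estimated correlation) and 0 calls adjusted over the list alone, with Kcnh1 at -0.22 and Kcnc1 at -0.18. Axon guidance and cell adhesion genes had 40 of 55 negative (median -0.09, adjusted p = 0.00353, and adjusted p = 0.678 with an estimated correlation), and 6 fell when adjusted over the list alone. Robo3, a guidance receptor, had -0.60, Sema7a -0.45 and Ntn4 -0.45. Over all genes 0 members of these 5 lists passed. With the GC-content trend removed, an alternative chosen after seeing the data, the medians were -0.03 for glutamate receptor (adjusted p = 0.0234), -0.05 for vesicle (0.0216) and -0.05 for calcium genes (0.00119). Dlgap4 then had -0.18, Shank1 -0.20, Cacna1i -0.19, Kcnc1 -0.01 and Sema7a -0.27.

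Glucocorticoid-induced genes, targets of the stress hormone receptor, rose as a group, with 15 of 22 positive (median 0.28, camera adjusted p = 8.3e-04, and adjusted p = 0.527 with an estimated correlation). Over all genes 0 passed, and 8 rose when adjusted over the list alone. Hif3a was at 26.8 ± 3.78 against 16.7 ± 2.90 CPM (0.68, adjusted p = 0.179), Sult1a1 had 0.51 (adjusted p = 0.173) and Pdk4 0.42 (adjusted p = 0.184). Ribosomal protein genes had 37 of 51 positive (median 0.11, adjusted p = 0.00582, and adjusted p = 0.668 with an estimated correlation). In that list 0 passed over all genes and 1 rose when adjusted over the list alone, with Rpl14 at 0.27 and Rpl7 at 0.25. Blood cell genes had 6 of 7 positive (median 1.49, adjusted p = 0.0119, and adjusted p = 0.637 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. The neutrophil genes S100a8, S100a9 and Ngp had 2.78, 3.04 and 2.76, and in post-extinction ABX replicate 1 stood at 2.17, 3.62 and 2.26 CPM. In the other 3 ABX libraries they reached at most 0.165, 0.165 and 0.0604 CPM, under the highest non-ABX library (0.246, 0.321 and 0.246 CPM), so these folds rest on replicate 1. Of the immediate early genes, whose median was -0.05, mean 0.06 and camera direction upward (adjusted p = 0.644), 0 passed over all genes or adjusted over the list alone. Ptgs2 had 0.38 (adjusted p = 0.186), Fosb 0.43 and Maff 0.71.

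The 3 genes called after extinction came beside 2234 genes at an unadjusted p under 0.05 (841 by chance), the libraries did not overlap for 1867 genes, 11.1% against 2.86% by chance, and the other 28 lists had adjusted p from 0.0516 to 0.876. All 3 calls held without post-extinction ABX replicate 1, where 6 genes were called, and 0 genes were called without any other single library of these groups. Among those 7 fits the adjusted p ran from 0.0602 to 0.189 for Krt9, from 0.0742 to 0.254 for Pkp2 and from 0.0742 to 0.296 for Npnt. Over all 8 fits with 1 library left out their fold changes ran from 0.57 to 0.66, from 0.66 to 0.79 and from -0.55 to -0.46. Without post-extinction ABX replicate 1 the lists for glutamate receptors (adjusted p = 0.126), calcium (0.0791), axon guidance (0.0712) and ribosomal proteins (0.0712) no longer passed, and without post-extinction non-ABX replicate 4 neither did axon guidance (0.133), ribosomal proteins (0.114) and blood cells (0.073). Blood cells also missed without post-extinction non-ABX replicate 3 (median 1.22 in voom values, where all libraries give 2.03, adjusted p = 0.0673), and could not be tested without post-extinction ABX replicate 1 or post-extinction non-ABX replicate 2, where too few members passed the filter. The calcium median was -0.13 without post-extinction non-ABX replicate 1, the axon guidance median -0.05 without post-extinction ABX replicate 4, and the ribosomal median 0.06 without post-extinction non-ABX replicate 2. With 3 libraries rich in blood transcripts left out, an alternative chosen after seeing the data, 1 gene was called and the glutamate receptor, calcium, axon guidance and ribosomal lists had adjusted p of 0.207, 0.0968, 0.057 and 0.0691. DESeq2 called 182 genes, voom with quality weights 306 and edgeR with the GC-content trend removed 67.

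**Figure D2:**
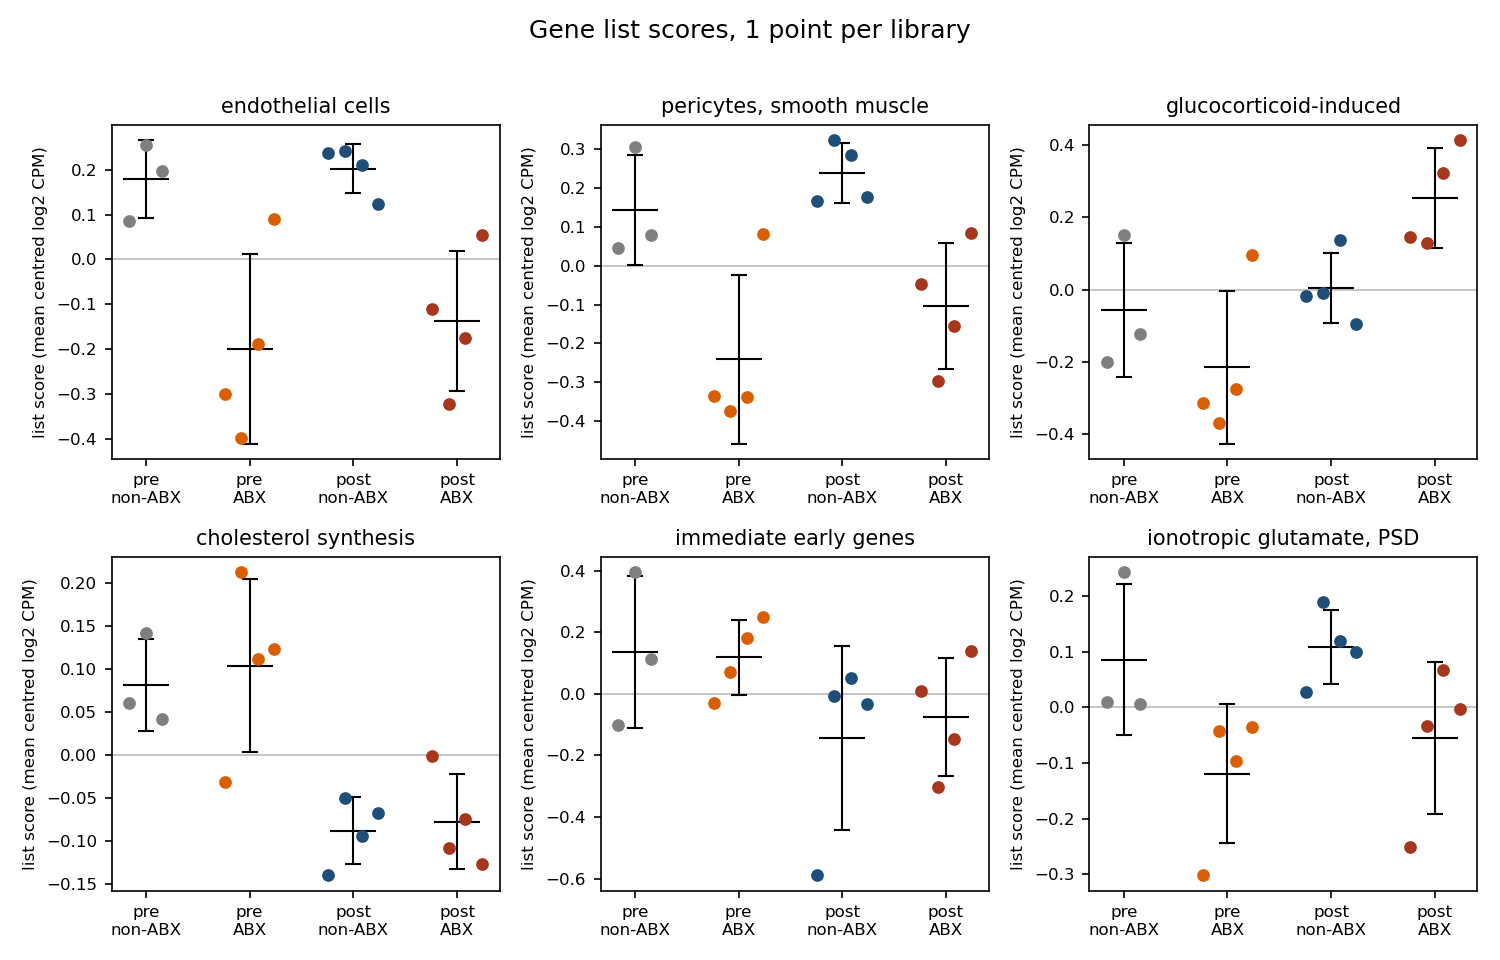
Score of 6 gene lists, the mean centred log2 CPM of their members (y axis), in the 4 groups (x axis), with 1 point per library, the mean as a long line and the SD as bars. The glucocorticoid score is highest in the 4 post-extinction ABX libraries taken as a group, and the immediate early gene score of 1 post-extinction non-ABX library lies at -0.59.

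The stage comparison in non-ABX mice asks which genes differed between mPFC sampled after and before extinction without the treatment. Cholesterol synthesis and uptake genes fell as a group, with 20 of 23 negative (median -0.17, camera adjusted p = 2.1e-08, and adjusted p = 0.33 with an estimated correlation). In this list 0 passed over all genes and 9 fell when adjusted over the list alone. Cyp51, lanosterol demethylase, was at 65.3 ± 2.87 CPM (SD, n = 4) after and 84.9 ± 5.65 CPM (SD, n = 3) before extinction (-0.38, edgeR adjusted p = 0.41), and Insig1, a sterol sensor partner, at 45.0 ± 0.416 against 56.7 ± 2.45 CPM (-0.33, adjusted p = 0.575). Immediate early genes fell as a group, with 30 of 32 negative (median -0.25, adjusted p = 5.5e-08, and adjusted p = 0.779 with an estimated correlation), and 3 fell when adjusted over the list alone.

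The orphan nuclear receptor genes Nr4a2 and Nr4a3 had -0.47 (adjusted p = 0.629) and -0.65 (adjusted p = 0.714), and the zinc finger factor Egr2 was at 6.67 ± 2.41 against 12.4 ± 2.02 CPM (-0.90, adjusted p = 0.697). Genes of deep-layer excitatory neurons, a list that also holds Nr4a2, fell as a group with 22 of 28 negative (median -0.15, camera adjusted p = 0.00826, and adjusted p = 0.923 with an estimated correlation). Bcl11b, a factor of subcerebral projection neurons, had -0.21 and Pou3f1 0.26 (adjusted p = 0.896 each). Genes of meningeal and perivascular fibroblasts rose as a group, with 24 of 26 positive (median 0.13, adjusted p = 0.00181, and adjusted p = 0.923 with an estimated correlation). Mgp, matrix Gla protein, had 0.48, Foxd1 0.71 and Fbln1 0.34 (adjusted p = 0.896 each). In the immediate early gene, deep-layer and fibroblast lists 0 genes passed over all genes, and in the deep-layer and fibroblast lists 0 passed when adjusted over the list alone. Among single genes that did not pass, Pde10a, a phosphodiesterase abundant in striatal projection neurons, was at 156 ± 19.8 against 105 ± 12.2 CPM (0.57, adjusted p = 0.382). The striatal marker list stood at 3.27 ± 0.04 and 3.21 ± 0.11 mean log2 CPM in these groups. Prr16 had 0.54 (0.382), Sertad3 0.53 (0.547), the lymphatic endothelial gene Lyve1 0.89 and Maml3 0.72 (0.575 each). Myh6 had -1.06 (adjusted p = 0.0969), Kcnh7, an ether-a-go-go related potassium channel, -0.95 (0.298), and Ago3, Kctd16 and Zbed6 had -0.68, -0.49 and -0.58 (0.355 each).

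In this comparison edgeR called 0 genes, with 830 at an unadjusted p under 0.05 where chance gives 841, while DESeq2 called 19 and voom with quality weights 3191. The libraries did not overlap for 993 genes, 5.91% against 5.71% by chance, and the other 34 lists had adjusted p from 0.0535 to 0.953. Leaving out pre-extinction non-ABX replicate 3 or post-extinction non-ABX replicate 4 gave 1 gene each, and leaving out pre-extinction non-ABX replicate 1 or post-extinction non-ABX replicate 4 gave 12 and 9 lists. Without pre-extinction non-ABX replicate 3 the immediate early genes (adjusted p = 0.0647) and deep-layer genes (median -0.10, adjusted p = 0.374) no longer passed. The immediate early median was -0.15 without post-extinction non-ABX replicate 1, where deep-layer genes (-0.10, adjusted p = 0.167) and fibroblast genes (0.07, adjusted p = 0.135) missed. The fibroblast list also missed without pre-extinction non-ABX replicate 4 (0.04, adjusted p = 0.461) and with 1 surrogate variable (0.07, adjusted p = 0.0739). Its median was 0.21 without pre-extinction non-ABX replicate 3 and 0.23 without post-extinction non-ABX replicate 4, where the deep-layer median was -0.24.

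The stage comparison in ABX mice asks the same question under the treatment. Plin4 (Entrez 57435, chromosome 17, 56100587 to 56109948), a lipid droplet perilipin, rose from 2.92 ± 1.54 to 15.3 ± 8.24 CPM (SD, n = 4 each), a log2 fold change of 2.39 (SE 0.35, edgeR adjusted p = 0.0161). Fmo2 (Entrez 55990, chromosome 1, 162874317 to 162898758), a flavin monooxygenase, rose from 1.25 ± 0.233 to 3.07 ± 0.373 CPM (1.30, SE 0.13, adjusted p = 6.5e-04). Fkbp5 (Entrez 14229, chromosome 17, 28398753 to 28486149), a chaperone partner of the glucocorticoid receptor, rose from 33.6 ± 8.01 to 57.7 ± 7.90 CPM (0.78, SE 0.13, adjusted p = 0.0329). Hif3a, a hypoxia-inducible factor subunit and with Plin4 and Fkbp5 a member of the glucocorticoid list, rose from 11.5 ± 3.69 to 26.8 ± 3.78 CPM (1.22, SE 0.19, adjusted p = 0.0183). Kcnh7 (Entrez 170738, chromosome 2, 62693410 to 63184287) fell from 29.9 ± 4.84 to 15.3 ± 1.37 CPM (-0.96, SE 0.16, adjusted p = 0.0253).

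Pkp2 rose by 0.90 (adjusted p = 0.00283), Smim3 by 0.80 (0.00365), Kirrel2, an adhesion molecule, by 0.81 (0.0445), Mthfd1l, a mitochondrial folate enzyme, by 0.47 (0.0329), Wipf3 by 0.44 (0.0236) and Per3, a circadian period gene, by 0.40 (0.0236). Pcdh11x, a protocadherin, fell by 0.65 (adjusted p = 0.0183) and Ptar1 fell by 0.78 (0.0445) on the log2 scale. Ptar1 no longer passed with the stricter filter (adjusted p = 0.051) or with the GC-content trend removed, an alternative chosen after seeing the data (-0.60, adjusted p = 0.088), and Kirrel2 missed with the stricter filter (0.0525) and the replicate block (0.078). Glucocorticoid-induced genes rose as a group, with 16 of 22 positive (median 0.45, camera adjusted p = 2.7e-05, and adjusted p = 0.716 with an estimated correlation). In this list 3 rose over all genes, and 12 rose and 1 fell when adjusted over the list alone. Cholesterol synthesis and uptake genes fell, with 19 of 23 negative (median -0.22, adjusted p = 1.1e-05, and adjusted p = 0.716 with an estimated correlation). Over all genes 0 of them passed, and 13 fell when adjusted over the list alone, with Insig1 at -0.41 (adjusted p = 0.0658) and Cyp51 at -0.35 (0.103).

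Immediate early genes fell as a group, with 24 of 32 negative (median -0.24, camera adjusted p = 6.6e-04, and adjusted p = 0.82 with an estimated correlation), and 7 fell when adjusted over the list alone. Fosl2, an AP-1 subunit, was at 31.3 ± 1.10 against 44.4 ± 4.61 CPM (-0.50, adjusted p = 0.052), with Tiparp at -0.56 (0.136) and Nr4a2 at -0.45 (0.138). GABA receptor and synthesis genes fell, with 16 of 20 negative (median -0.16, adjusted p = 1.8e-04, and adjusted p = 0.776 with an estimated correlation), and 5 fell when adjusted over the list alone. The receptor subunit genes Gabrb1, Gabrg3 and Gabrb2 had -0.55 (adjusted p = 0.0754), -0.58 (0.124) and -0.42 (0.159). Axon guidance and cell adhesion genes fell, with 40 of 55 negative (median -0.13, adjusted p = 1.8e-04, and adjusted p = 0.82 with an estimated correlation), and 11 fell and 2 rose when adjusted over the list alone. Pcdh9 had -0.36 (adjusted p = 0.068), and the netrin receptor genes Unc5d and Dcc -0.38 and -0.42 (0.0794 each). Ribosomal protein genes rose as a group, with 39 of 51 positive (median 0.16, adjusted p = 0.0086, and adjusted p = 0.82 with an estimated correlation). In the immediate early, GABA, axon guidance and ribosomal lists 0 genes passed over all genes, and in the ribosomal list 0 passed when adjusted over the list alone. Rps2 had 0.29 and Rpl37 0.23, while Rpl5 had -0.44 at 0.731 against 0.992 CPM, a low level in a gene with processed pseudogenes. With the GC-content trend removed the GABA median was -0.09 and the axon guidance median -0.07, Pcdh9 had -0.23, Pcdh11x -0.42, Rps2 0.14 and Rpl37 0.14.

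In ABX mice edgeR called 16 genes, 13 higher and 3 lower, with 2798 at an unadjusted p under 0.05 (841 by chance), libraries that did not overlap for 920 genes (5.47% against 2.86% by chance) and 32 other lists at adjusted p from 0.072 to 0.975. Outside the naming rule, and named after their values were seen, the called genes were Tef, Fcrl1 and Rtp1. Fmo2, Pkp2 and Smim3 held without any single library of the 2 groups (highest adjusted p 0.004, 0.0202 and 0.0253). The other 10 genes named as called were lost without pre-extinction ABX replicate 3 (adjusted p from 0.0856 to 0.212) or replicate 1 (0.0633 to 0.0966), and 9 without replicate 2. Without post-extinction ABX replicates 2, 3 and 4, 8, 9 and 9 of them were lost, and 1, Ptar1, without replicate 1 (adjusted p = 0.0605). Over these 8 fits the 10 genes kept their direction. Fold changes ran from 1.99 to 2.82 for Plin4, 1.04 to 1.42 for Hif3a, 0.70 to 0.95 for Fkbp5, 0.36 to 0.45 for Per3 and -1.03 to -0.86 for Kcnh7. The number of genes called was 3, 4, 4 and 237 without pre-extinction ABX replicates 1 to 4, and 43, 5, 5 and 4 without post-extinction ABX replicates 1 to 4. The ribosomal list missed without post-extinction ABX replicate 1 (median 0.08, adjusted p = 0.282), and the immediate early median was -0.14 without pre-extinction ABX replicate 3. With the 3 libraries rich in blood transcripts left out, Fmo2 and Pkp2 alone were called and the ribosomal list missed (adjusted p = 0.299). DESeq2 called 282 genes, voom with quality weights 465 and edgeR with the GC-content trend removed 68.

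The interaction asks whether the stage difference itself differed between ABX and non-ABX mice. Glucocorticoid-induced genes had a more positive stage difference with ABX in 20 of 22 members (median interaction 0.39, camera adjusted p = 5.1e-11, and adjusted p = 0.203 with an estimated correlation), and 3 passed upward when adjusted over the list alone. This call held without any single library (highest adjusted p 2.1e-06). GABA genes had 17 of 20 negative (median -0.07), myelin genes 19 of 29 (-0.07), interferon response genes 22 of 30 (-0.12) and axon guidance genes 40 of 55 (-0.09), while deep-layer neuron genes had 19 of 28 positive (0.16). Their camera adjusted p was 0.0142, and 0.0174 for myelin, and 0.929 to 0.93 with an estimated correlation. For single genes edgeR called 0, with 346 at an unadjusted p under 0.05 (841 by chance), while DESeq2 called 4 and voom with quality weights 0. The genes with the smallest p were Myh6 (1.24), Pkp2 (0.81), Prr16 (-0.76) and Fmo2 (0.95), each at adjusted p = 0.564, and Entrez 100502895, which has no symbol in the annotation used (0.93, adjusted p = 1). The other 32 lists had adjusted p from 0.0668 to 0.907, and 0 members of any of the 6 called lists passed over all genes.

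The number of lists was 3 without pre-extinction ABX replicate 4. Each of the 5 interaction lists apart from the glucocorticoid list lost its call without at least 1 single library. The GABA list missed without pre-extinction ABX replicate 3 (adjusted p = 0.126), pre-extinction non-ABX replicate 3 (0.33) or post-extinction non-ABX replicate 4 (0.0631), and the highest value was 0.619 for myelin, 0.679 for interferon, 0.284 for deep-layer and 0.35 for axon guidance genes. The deep-layer list also missed with 1 surrogate variable (0.0609) and the axon guidance list with the replicate block (0.15).

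Whether the same genes moved with stage in both arms was counted directly. Over all genes 0 genes were called by edgeR in both stage comparisons, 8 by DESeq2 and 253 by voom with quality weights. At an unadjusted p under 0.05 in both, 83 genes were higher after extinction in both arms where independence gives 19.5, 325 were lower in both (51.7) and 4 went opposite ways. Kcnh7 was at 29.9 and 29.7 CPM before extinction and at 15.3 and 15.4 CPM after it in the ABX and non-ABX groups, and the cholesterol and immediate early gene lists were called lower in both. In non-ABX mice the immediate early call was lost without pre-extinction non-ABX replicate 3 (camera adjusted p = 0.0647). For the ABX comparisons before and after extinction, 235 genes were higher in both (49.6 by independence), 574 lower in both (131) and 5 opposite. The comparisons of each pair share no library, and the endothelial, pericyte and glutamate receptor lists were called lower in both. The glutamate receptor call after extinction was lost without post-extinction ABX replicate 1 (camera adjusted p = 0.126). With an estimated correlation 0 lists passed in any of these comparisons. The values by independence take no account of genes that move together. The slope of expression on GC content differed in the same direction within each pair. In log2 CPM per 10 percentage points the differences were 0.13 and 0.21 for stage and -0.25 and -0.16 for ABX. The excesses therefore cannot be told apart from a shared GC-content trend.

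Some lists of other cell types and pathways that did not pass in any pairwise comparison had small medians in the ABX comparisons. Those of myelin and upper-layer neuron genes after extinction were as large as the medians of some neuronal lists that were called. Microglial genes had 0.04 before (camera adjusted p = 0.853) and 0.00 after extinction (0.876) in the ABX comparison, astrocyte genes 0.01 (0.759) and -0.04 (0.644), and myelin genes 0.00 and, after extinction, -0.12 (0.0891). Interneuron markers had 0.01 (0.853) and -0.05 (0.424), upper-layer neuron genes -0.02 (0.759) and -0.11 (0.138), and circadian clock genes -0.04 (0.53) and 0.02 (0.644). Genes of tryptophan, phenol and xenobiotic metabolism, pathways that handle products of gut bacteria, had 0.10 (0.305) and 0.07 (0.0645).

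The libraries differed along a gradient of gene GC content that was not the same as the groups. The first principal component held 40.4% of the variance, and across genes, which are not independent replicates, its loadings followed GC content with a Spearman rho of 0.823. The slope of expression on GC content, in log2 CPM per 10 percentage points, averaged -0.21 ± 0.20 in pre-extinction ABX, 0.04 ± 0.25 in pre-extinction non-ABX, 0.01 ± 0.13 in post-extinction ABX and 0.17 ± 0.10 in post-extinction non-ABX libraries. By two-sided exact permutation tests the slope difference had p = 0.229 and 0.114 for ABX before and after extinction, and p = 0.371 and 0.114 for stage without and with ABX, with 0.0286 the smallest p possible. Mitochondrial transcripts took 4.76 ± 1.15% of counts in pre-extinction ABX, 3.93 ± 0.802% in pre-extinction non-ABX, 4.35 ± 0.731% in post-extinction ABX and 3.88 ± 0.639% in post-extinction non-ABX libraries. The blood cell list was highest in post-extinction ABX replicate 1, at 0.66 mean log2 CPM, followed by pre-extinction ABX replicate 1 at -0.94 and post-extinction non-ABX replicate 2 at -0.95.

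**Figure D3:**
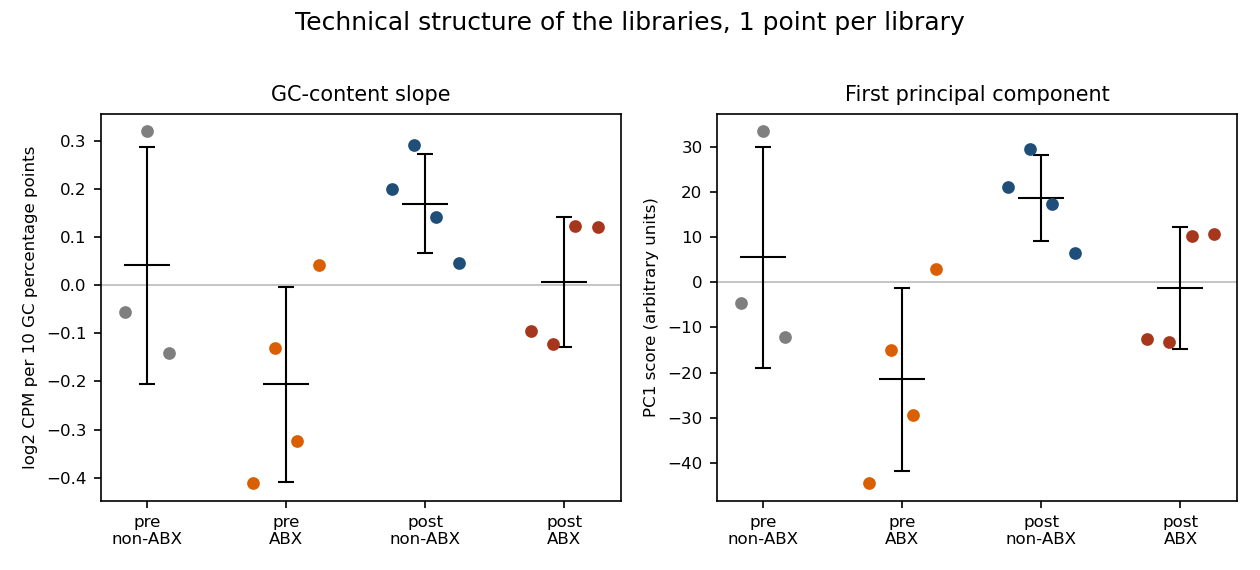
Slope of expression on gene GC content in log2 CPM per 10 percentage points (left) and score on the first principal component in arbitrary units (right) for the 4 groups, with 1 point per library, the mean as a long line and the SD as bars. Pre-extinction ABX libraries average a slope of -0.21 and post-extinction non-ABX libraries 0.17, with the means of the other groups between them.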

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

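The tests in this part of single libraries, of other splits of the samples, of clock time, and of the GC-content trend as the cause of the vascular and glucocorticoid patterns were chosen after the results were seen.

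Endothelial and mural cell genes were called lower in ABX libraries at both stages by camera with the preset correlation. Before extinction the list scores of single libraries overlapped. Pre-extinction ABX replicate 4 had 0.091 for endothelial and 0.082 for pericyte genes, above pre-extinction non-ABX replicate 1 at 0.085 and 0.045. After extinction the scores of the ABX and non-ABX libraries did not overlap in either list. The tables argue against the GC-content trend as the whole cause, since with it removed the endothelial score of the averaged ABX contrast still differed (two-sided exact permutation p = 0.00122). They also argue against a single library, since with 1 library left out the endothelial median of that contrast stayed between -0.36 and -0.26 in voom values. The highest camera adjusted p in those fits was 4.7e-09 (adjusted p = 0.799 with an estimated correlation and all libraries). Camera with the preset correlation called as many lists in most other splits, so this p adds little. Fewer vascular cells in the ABX samples stays open and could account for the pattern. A set of 8 markers largely restricted to endothelium averaged a log2 difference of -0.34 (SE 0.08, exact permutation p = 0.00245) beside a list median of -0.30. All 8 are members of the endothelial list, scored in the same libraries. Their fall was therefore tied to that of the list and gives no separate support for fewer cells. Among them Slco1a4 had -0.09 (adjusted p = 0.600) and Cldn5 -0.69. With the GC-content trend removed Slco1a4 had -0.20 and Cldn5 -0.40, and the 8 lay between -0.20 and -0.47. Lower transcription of these genes in each cell cannot be separated from fewer cells in bulk tissue, and a difference in dissection between the groups was not tested. An effect of the ABX treatment, which the design names, also stays open as a hypothesis.

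Glucocorticoid-induced genes were higher after extinction in ABX libraries. The tables argue against the GC-content trend as the whole cause, since the list's median was 0.32 with the trend removed. They also argue against a single library, since with 1 library left out the median stayed between 0.37 and 0.57 in voom values. The highest camera adjusted p in those fits was 9.0e-04 (adjusted p = 0.716 with an estimated correlation and all libraries). Camera with the preset correlation called as many lists in most other splits, so this p adds little. A different clock time at collection could contribute: genes of opposite phases of the clock (Dbp, Tef, Per3, Ciart, Per2 and Nr1d2 against Arntl, Npas2, Clock and Nfil3) moved apart by 0.60 log2 between the pre-extinction and post-extinction ABX libraries, by 0.57 without Tef and Per3, which were called in this comparison, and by 0.49 with Hlf and Nr1d1 added to those left (two-sided exact permutation p = 0.0286 each, the smallest possible). The same measure was 0.21 for stage in non-ABX mice and 0.13 for ABX after extinction (exact permutation p = 0.0571 each) and -0.27 for ABX before extinction (exact permutation p = 0.257), with the other 2 gene sets 0.16 and 0.16 (exact permutation p = 0.2 and 0.171), 0.11 and 0.038 (0.0857 and 0.571) and -0.30 and -0.29 (0.257 each), and the collection time is not given in the sources used here. A stress response that differs with ABX treatment stays open as a hypothesis, untested.

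More genes were called for ABX after extinction once the GC-content trend was removed, 67 against 3. Spread that the trend adds between libraries may account for the rise, and the biological coefficient of variation went from 0.112 to 0.0765, a fall of 31.4%. Subtracting a trend fitted to each library lowers such spread in itself, so the fall cannot decide this. It also applies to every contrast. Calls stayed at 1 for ABX before extinction, went from 0 to 2 for stage in non-ABX mice and from 16 to 68 in ABX mice. The tables argue against distortion of genes at extreme GC content, since 10.4% of the 67 lay in the outer 5% of GC content at either end, where an even spread gives 10%. The trend itself may come from library preparation or from RNA quality, and neither was tested.

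Other splits of the same libraries were refitted to see how often chance gives as many calls. For genes called with ABX after extinction 1 of 35 splits, the real one, was as large (3 genes, highest other 0). For stage in ABX mice it was also 1 of 35 (16 genes, highest other 3). These shares lie under 5% but are the smallest that 35 splits can give, and they were not adjusted over the counts tested. They speak against chance without excluding it. Where the non-ABX libraries were regrouped as well, 3 of 100 draws, the real one included, gave 16 genes or more for stage in ABX mice, the highest other 3862, and the highest for stage in non-ABX mice was 1494, which points to a structure of the samples. For ABX before extinction chance stays open, with 3 of 35 splits giving at least 1 gene and the highest other 2757. That split set pre-extinction ABX replicates 1, 2 and 3 and non-ABX replicate 4 against the rest, libraries with the lowest GC slopes, and points to a structure of the samples along GC content. Where the real count is 0 every split gives as many, so the splits say nothing about chance for stage in non-ABX mice (35 of 35, highest other 0), the interaction (100 of 100, highest other 5843) and the genes called in both stage comparisons (100 of 100, highest other 0). For the averaged contrasts the shares from 100 draws lay under the 5% limit, which does not exclude chance. They were 4 of 100 for ABX (105 genes, highest other 5843) and 2 of 100 for stage (162 genes, highest other 4477). The splits with those high counts again point to a structure of the samples.

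With the GC-content trend removed, 2 of 35 splits gave at least the 1 gene of ABX before extinction (highest other 30), so chance cannot be excluded there. Only the real split reached the 67 genes of ABX after extinction (1 of 35, highest other 0). The real split alone also reached the 68 of stage in ABX mice (1 of 35, highest other 50). Only the real draw reached the 702 of the averaged ABX contrast (1 of 100, highest other 484). These shares are the smallest that 35 splits or 100 draws can give. They were not adjusted over the counts tested, and the removal of the trend was chosen after seeing the data. They speak against chance without excluding it. For the number of gene lists called chance cannot be excluded in any contrast. As many lists came in 32 of 35 splits for ABX before extinction (real 4, highest other 22) and 24 of 35 after (10, highest other 21). For stage it was 33 of 35 in non-ABX (4, highest other 23) and 32 of 35 in ABX mice (6, highest other 26). The interaction had 73 of 100 (6, highest other 24), averaged ABX 78 of 100 (7, highest other 24) and averaged stage 76 of 100 (6, highest other 21).

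Single libraries far from the others of their group were found in 10 of 192 groups of 4 values, where chance gives 9.6. In post-extinction non-ABX replicate 1 the immediate early gene score was -0.59 (nearest other -0.03) and the calcium score -0.040 (nearest 0.08). In post-extinction non-ABX replicate 4 the oligodendrocyte precursor score was 0.063 (nearest 0.15) and the upper-layer score 0.022 (nearest 0.09). In post-extinction ABX replicate 1 the interferon score was 0.34 (nearest -0.15) and the blood score 2.90 (nearest 0.35), and in replicate 2 the meningeal fibroblast score was -0.19 (nearest 0.03). In pre-extinction ABX replicate 1 the blood score was 1.30 (nearest -0.48), and in replicate 4 the pericyte score was 0.082 (nearest -0.34) and Tef, a circadian output gene, stood at 450.0 CPM (nearest 411).

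For the interaction, camera with the preset correlation called 6 lists. Their median interaction log2 fold changes were -0.066 for GABA, 0.39 for glucocorticoid-induced, -0.070 for myelin, -0.12 for interferon response, 0.16 for deep-layer neuron and -0.089 for axon guidance genes. As many lists came in 73 of 100 splits, so this number of calls does not show that the stage difference itself differed between ABX and non-ABX mice. With an estimated correlation 0 of these lists passed, and the interferon median was 0.02 without pre-extinction ABX replicate 4.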

How the results depend on the processing

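All alternatives here were planned except the removal of the GC-content trend, the omission of the 3 libraries with most blood transcripts (below, blood-rich) and the averaged contrasts, which were chosen after seeing the data. Across planned settings, with averaged contrasts counted in, the named genes kept their direction and side of the threshold in 1273 fits, crossed it in 158 upward and 48 downward and reversed in 3; lists kept theirs in 209, lost the call in 89 and reversed in 2. With 1 library left out these were 1584, 40 and 439 for genes and 404 and 63 for lists, with 0 reversed in the test's direction, although the interferon median of the interaction was 0.02 in voom values without pre-extinction ABX replicate 4 (adjusted p = 0.679) against -0.096 with all libraries. The cause of a change was not tested unless stated.

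Genes called for ABX before extinction (1) were 15 by DESeq2 and 2 with no filter. After extinction (3) they were 182 by DESeq2, 306 by voom with quality weights, 20 with 1 surrogate variable, 67 with the GC trend removed, 1 without blood-rich libraries and 32 in the 2 groups alone. For stage in non-ABX mice (0) they were 19 by DESeq2, 3191 by voom, 2 with no filter, 3 with the surrogate variable and 2 with the GC trend removed. In ABX mice (16) they were 282 by DESeq2, 465 by voom, 32 with the surrogate variable, 68 with the GC trend removed, 2 without blood-rich libraries and 5 in the 2 groups alone. The interaction (0) had 4 by DESeq2, and genes called in both stage comparisons (0) were 8 by DESeq2 and 253 by voom. Averaged ABX (105) had 1977 by DESeq2, 902 by voom, 4 with the surrogate variable, 702 with the GC trend removed and 1 without blood-rich libraries. Averaged stage (162) had 704, 6358, 320 with the GC trend removed and 83 without blood-rich libraries.

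With an estimated correlation 0 lists passed in all 7 contrasts, and fry called 0 in the 5 planned contrasts, 2 for averaged ABX and 1 for averaged stage. With the surrogate variable lists called were 15 and 19 for ABX before and after extinction, 10 and 11 for stage in non-ABX and ABX mice and 16 for averaged ABX. With the GC trend removed they were 7, 10 and 10 for stage in non-ABX and ABX mice and averaged stage.

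Replicate numbers showed no steady pairing of the samples, with correlations of the same number across groups from -0.49 to 0.37 and 5 of 15 libraries closest to their own number. These values do not settle whether the numbers mark something shared, which the labels do not say. As a block the replicate numbers gave 666 genes for averaged ABX and 96 for averaged stage, and 7 and 9 lists for ABX before extinction and stage in non-ABX mice.

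With the surrogate variable these reversed: mt-Nd6 (-0.016) and the mitochondrial list (-0.077) for ABX before extinction, and mt-Rnr1 (-0.0058), mt-Nd6 (-0.046) and the mitochondrial list (-0.095) for averaged ABX. Kcnc1 was 0.042 for averaged ABX with the GC trend removed. The mitochondrial list before extinction also missed with the GC trend removed (adjusted p = 0.603, range 8.5e-05 to 0.89 over settings). Leaving out each library in turn, genes called ran from 1 to 28 and from 0 to 6 for ABX before and after extinction, from 0 to 1 and from 3 to 237 for stage in non-ABX and ABX mice, from 0 to 0 for the interaction, from 0 to 1 for both stage comparisons, from 4 to 3057 for averaged ABX and from 14 to 2262 for averaged stage. Lists ran from 4 to 8, 8 to 14, 3 to 12, 6 to 8, 3 to 9, 5 to 9 and 4 to 9 in the same order without the count for both. Depth limits genes of low level, several of those named among them. With RLE scaling and with the stricter filter every count stayed within 1.5 times.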

Other observations

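The tests of the averaged contrasts in this part were chosen after the data were seen. Averaged over both stages, 9 of 38 list scores passed the adjusted exact test, each lower in ABX libraries. The endothelial score was lower by a log2 difference of -0.36 (two-sided exact permutation p = 0.00163, adjusted p = 0.031 over 38 lists) and the pericyte score by -0.36 (p = 0.00245, 0.031). The glutamate receptor and postsynaptic density score had -0.18 (exact p = 0.00163, 0.031), synaptic vesicle genes -0.10 (0.00367, 0.0341), upper-layer neurons -0.09 (0.00449, 0.0341), calcium -0.11 (0.00571, 0.0362), potassium channels -0.10 (0.00735, 0.0399), oligodendrocyte precursors -0.15 (0.0102, 0.0485) and metabotropic glutamate receptors -0.15 (0.0118, 0.04998). By camera the upper-layer, precursor and metabotropic lists were not called (lowest adjusted p of the uncalled lists 0.124). GABA genes had -0.0045 (exact p = 0.902) and dendritic spine genes -0.06 (adjusted p = 0.0592). By edgeR 105 genes were called, 27 higher and 78 lower. Among those that fell, Podxl had -0.53 (adjusted p = 0.0053), Flt1 -0.48 (0.0323), Nos3, the endothelial nitric oxide synthase, -0.78 (0.0372), Acta2 -0.90 (0.0313), Pltp -0.86 (0.00669), Cacng2 -0.38 (0.0372), Atp2b2 -0.36 (0.0372) and Cacna1i -0.40 (0.0372), the last of which had -0.12 (0.123) with the GC-content trend removed. Higher were Krt9 (0.51, 0.0053), Utp14b (0.47, 0.0176), Car13, a cytosolic carbonic anhydrase (0.57, 0.0372), and Etnppl, an ethanolamine-phosphate phospho-lyase (0.79, 0.0361). In the endothelial list 7 of 27 genes fell over all genes and 20 when adjusted over the list alone (camera adjusted p = 2.6e-12, adjusted p = 0.799 with an estimated correlation). The gene count changed with the library left out: it was 11, 13, 11 and 3057 without pre-extinction ABX replicates 1 to 4, 30, 4 and 1052 without pre-extinction non-ABX replicates 1, 3 and 4, 15, 14, 64 and 56 without post-extinction ABX replicates 1 to 4, and 16, 4, 5 and 87 without post-extinction non-ABX replicates 1 to 4. Fold changes moved less over these 15 fits, from -0.58 to -0.48 for Podxl, -0.54 to -0.44 for Flt1, -0.90 to -0.60 for Nos3 and 0.49 to 0.54 for Krt9. The gene count was 4 with 1 surrogate variable and 1 without the 3 libraries rich in blood transcripts, against 702 with the GC-content trend removed. In that last fit the glutamate receptor median was -0.04, where all libraries without the removal give -0.19.

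Averaged over both arms, mPFC after extinction had lower cholesterol synthesis genes. The cholesterol score differed by -0.18 (two-sided exact permutation p = 8.2e-04, adjusted p = 0.031 over 38 lists), and 7 of 23 genes fell over all genes and 13 when adjusted over the list alone (camera adjusted p = 2.2e-07, adjusted p = 0.469 with an estimated correlation). Insig1 had -0.37 (edgeR adjusted p = 0.0115) and Cyp51 -0.36 (0.0121). The scores of GABA, glucocorticoid-induced and immediate early genes had exact p of 0.00449, 0.0208 and 0.0547 (adjusted 0.0853, 0.192 and 0.24), so none of these 3 passed. Of the immediate early genes Fosl2 had -0.37 (edgeR adjusted p = 0.0216), Nr4a2 -0.46 (0.0226), Egr2 -0.88 (0.0322) and Nr4a3 -0.62 (0.0379). By edgeR 162 genes were called, 37 higher and 125 lower, with Plin4 at 1.69 (0.0101), Fmo2 at 0.82 (0.00279), Fkbp5 at 0.51 (0.0216), Kcnh7 at -0.96 (0.00279), Gabrb1 at -0.56 (0.0111) and Fabp7, a fatty acid binding protein of radial glia and astrocytes, at -0.82 (0.0119). The stage count was 121, 82, 33 and 747 without pre-extinction ABX replicates 1 to 4, and 22, 2262 and 14 without pre-extinction non-ABX replicates 1, 3 and 4. Without post-extinction ABX replicates 1 to 4 it was 175, 168, 47 and 43, and without post-extinction non-ABX replicates 1 to 4 it was 45, 70, 20 and 269.

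Transcripts typical of heart muscle, chosen after their values were seen, averaged 4.87 CPM (Myh6), 0.898 CPM (Mb), 0.682 CPM (Nppa) and 0.803 CPM (Myl2) in the 3 pre-extinction non-ABX libraries, against 1.45, 0.399, 0.451 and 0.363 CPM in pre-extinction ABX, 2.33, 0.459, 0.374 and 0.354 CPM in post-extinction non-ABX and 1.64, 0.347, 0.415 and 0.363 CPM in post-extinction ABX libraries. Other heart muscle transcripts differed less or in another order: in the same order of groups Myh7 had 6.78, 4.96, 6.63 and 5.82 CPM, Tnni3 0.443, 0.189, 0.290 and 0.378 CPM and Tnnt2 10.3, 9.54, 8.87 and 10.9 CPM.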
